A study of Danio rerio with 6 samples.

How the data were processed

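Poly-A RNA was sequenced from adult zebrafish of the Tg(aanat2:EGFP) line, aged 0.5 to 1.5 years and kept in 12 h of light and 12 h of dark. In this line the control region of aanat2, a gene of melatonin synthesis, drives a green fluorescent protein that marks the pineal gland. Pineal glands, whole eyes and a mixture of other organs were collected 6 h (ZT6, day) and 18 h (ZT18, night) after lights came on. A pineal library held 18 glands and an eye library 6 eyes. The mixed library held equal amounts of RNA from brain, heart, gill, intestine, kidney, liver, muscle and ovary, each from 4 to 8 fish. There were 6 libraries, 1 for each tissue and time point, so each tissue had 2 libraries and none was repeated at the same time point.

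The authors deposited 1 table of FPKM values (fragments scaled to gene length and library size) for 32105 genes. Per the submitters' processing notes, reads were checked with FastQC, aligned to danRer10 with STAR 2.3.0e and counted with featureCounts of the Subread package, and DESeq2 was used. The annotation release is not given in the sources used here. The table's columns of means were not used. Gene symbols came from a table that pairs gene IDs with symbols. It gave a symbol for 26269 of the 32105 IDs, many in the capitals of the human gene, and some symbols belong to more than 1 gene. IDs are therefore printed with the symbols. All 13 mitochondrially encoded genes were listed at 0 in all 6 libraries, so nothing is said of them.

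Whole reads were recovered from the steps of each gene's FPKM values. For all 27233 genes above 0 in any library the values were whole multiples of 1 read within a tolerance of 0.02 read, and 145978 of 146167 values were rebuilt to within 1e-6. The total reads behind the FPKM values were 11045259 (pineal day), 7949224 (pineal night), 15016838 (eye day), 13418642 (eye night), 15708307 (mixed day) and 15950819 (mixed night). The genes of the table held 99.6% to 99.9% of these totals. Intervals on the ratio of 2 libraries are 95% exact intervals (Clopper-Pearson) from these reads and cover counting error only. The units recovered could be reads or fragments, which the values do not show. If each fragment was counted as 2 reads, the intervals are too narrow. For 583 genes a factor common to all libraries was put back because the gene length was otherwise not a whole number. Such a factor goes unseen where the length is whole without it, and the intervals are then too wide.

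Tissues were compared with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with tissue and time point as terms and all 6 libraries in 1 model. Variances were moderated with a mean trend (2 residual and 3.46 prior degrees of freedom). Genes with at least 1 FPKM in 2 or more libraries were tested, 21325 in all. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and at least a 2-fold change. Tests were two-sided. The 2 libraries of a tissue were a day and a night pool, so the spread behind each p-value is the departure of the 6 pools from additive effects of tissue and time. Log2 values are on the log2(FPKM + 1) scale, which understates the change of genes near 0, and each is given with its standard error (SE). The time term of the same model gave night against day over the 3 tissues.

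Within a tissue, night and day were 1 library each, so differences have no test and no replicate check. Genes with at least 5 FPKM in the higher library and at least a 2-fold difference were counted by size alone. The median of a gene list was placed among 10000 random lists matched on size and mean expression over 20 expression bins, as a description of these libraries. Overlaps of calls were set beside the number from independent lists and beside 50 simulations of unchanged groups that shared the mixed libraries.

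There were 32 gene lists, of tissues, cell types and pathways, fixed before the data were examined. Members without a match among the gene symbols could not be included. These were 5 of the non-visual and pineal opsins, exorh among them, 4 of the rod list, pde6a among them, and 5 of the erythrocyte list. Several other lists also lacked members. Lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. They were tested again with an estimated correlation. In that setting camera judges a list on the 2 residual degrees of freedom, so its p-values stay large even where the estimated correlation is small. The genes named here followed a rule that was also fixed before the data were examined. For each tissue comparison they were the 12 called genes with the largest rise and the 12 with the largest fall, with at least 10 FPKM in the higher tissue. Within each tissue they were the 12 largest differences on either side at night. Any member of a list could be named for the largest changes of that list, and any member of the clock and melatonin lists. Clone names and numbered loci were left out.

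The limma procedure was tested on simulated data for 21325 genes. Means came from the real libraries, variances were drawn from the fitted prior, and 200 genes were changed. The changed genes were drawn from those with higher means, and calls used the adjusted p alone, with no fold threshold. For pineal against mixed tissue it called 0% of 2-fold, 83% of 4-fold and 95.5% of 8-fold changes, with 0 calls of the wrong sign. For pineal against eye it called 0%, 77.5% and 92.5%, and for night against day 0%, 87% and 96.5%. Unchanged genes called in the same 9 simulations numbered 0 to 12. With only 200 changed genes the cut on the unadjusted p is stricter than in the real tissue comparisons. In pineal against mixed tissue 13353 genes passed the adjusted p, so the shares recovered do not describe the tissue comparisons. The counting intervals covered the known ratio in 95.5% to 96.6% of 1000 simulations. The range of random lists was left by 10% of 50 unshifted lists, more often than intended, and by 100% of lists shifted by 1 on the log2 scale.

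Alternatives covered the pseudocount (0.1), the filter on low values, the median ratio of the libraries, quantile normalization, moderation without the mean trend, the fold threshold, the terms and tissues of the model, and each library left out in turn. Alternatives added after the data were examined were voom (limma) on the recovered reads, limma with a robust prior, and the eye without genes far higher in mixed tissue. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.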

Results

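The transcriptomes of the zebrafish pineal gland, whole eye and a mixture of 8 other organs were measured at mid-day and mid-night. Each of the 6 libraries was 1 pool, with 7949224 to 15950819 reads behind its FPKM values. The design asks which transcripts set the pineal gland and the eye apart from other tissues and from each other, and which differ between day and night.

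Against mixed tissue, limma called 9920 of 21325 genes in the pineal gland, 3491 higher (35.2%) and 6429 lower. Quantile normalization changed that split to 5119 higher (52.0%) and 4722 lower. It moved the median log2 value of all genes from -0.28 to 0.06 in this comparison, from -0.19 to 0.02 in eye against mixed tissue and from -0.04 to 0.09 in pineal against eye. The values below far exceed these shifts unless stated. The largest rise was that of ASMT (ENSDARG00000098249), the enzyme of the last step of melatonin synthesis, at a log2 value of 10.72 (SE 0.23, limma adjusted p 1.29e-05). Most of the other genes with the largest rises act in phototransduction. GNAT1 (ENSDARG00000044199) was higher by 10.53 (SE 0.23), ARR3 (ENSDARG00000056511) by 10.08 (SE 0.16), PDE6B (ENSDARG00000000380) by 9.82 (SE 0.23), saga (ENSDARG00000012610) by 9.63 (SE 0.36) and rcvrna (ENSDARG00000052223) by 9.45 (SE 0.46). The retinol-binding gene rbp4l (ENSDARG00000044684) was higher by 10.01 (SE 0.36). Most of the 12 largest falls were yolk, egg coat and heart muscle genes. The log2 value was -9.52 (SE 0.23) for vtg1 (ENSDARG00000092233), -9.23 (SE 0.16) for zpax1 (ENSDARG00000069251), -9.13 (SE 0.17) for MYH7 (ENSDARG00000079782) and -8.80 (SE 0.20) for MYL7 (ENSDARG00000019096).

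Of 25 tested genes of melatonin synthesis and its cofactor supply, 13 were higher and 3 lower in the pineal gland than in mixed tissue (camera adjusted p 0.000374 preset, 0.190 with an estimated correlation). TPH2 (ENSDARG00000057239) was higher by 9.17 (SE 0.29) and TPH1 (ENSDARG00000029432) by 6.98 (SE 0.24); both encode tryptophan hydroxylases. The acetyltransferase gene aanat2 (ENSDARG00000079802) was higher by 9.10 (SE 0.53). Genes that supply the cofactor and the methyl donor were higher too: GCH1 (ENSDARG00000070453) by 6.96 (SE 0.60), MAT2A (ENSDARG00000040334) by 3.93 (SE 0.16) and QDPR (ENSDARG00000040190) by 2.35 (SE 0.20). Between night and day the list as a whole did not stand out in the pineal gland: over 16 members its median was 0.18 (random lists -0.32 to 0.20), with 10 above and 6 below 0. Some members were higher in the night library. In the pineal gland aanat2 was at 491 FPKM by day and 1922 at night, a ratio of 3.92 (95% exact interval 3.82 to 4.02). TPH1 (ENSDARG00000029432) went from 743 to 2290 FPKM, a ratio of 3.08 (3.03 to 3.14), and GCH1 from 333 to 978, a ratio of 2.94 (2.89 to 2.99). PTS (ENSDARG00000045269) had a ratio of 2.91 (2.55 to 3.32). AHCY (ENSDARG00000005191), which clears the product of methylation, had the opposite difference, 1192 FPKM by day and 463 at night. ASMT differed less, with 2814 FPKM by day and 2283 at night.

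**Figure D1:**
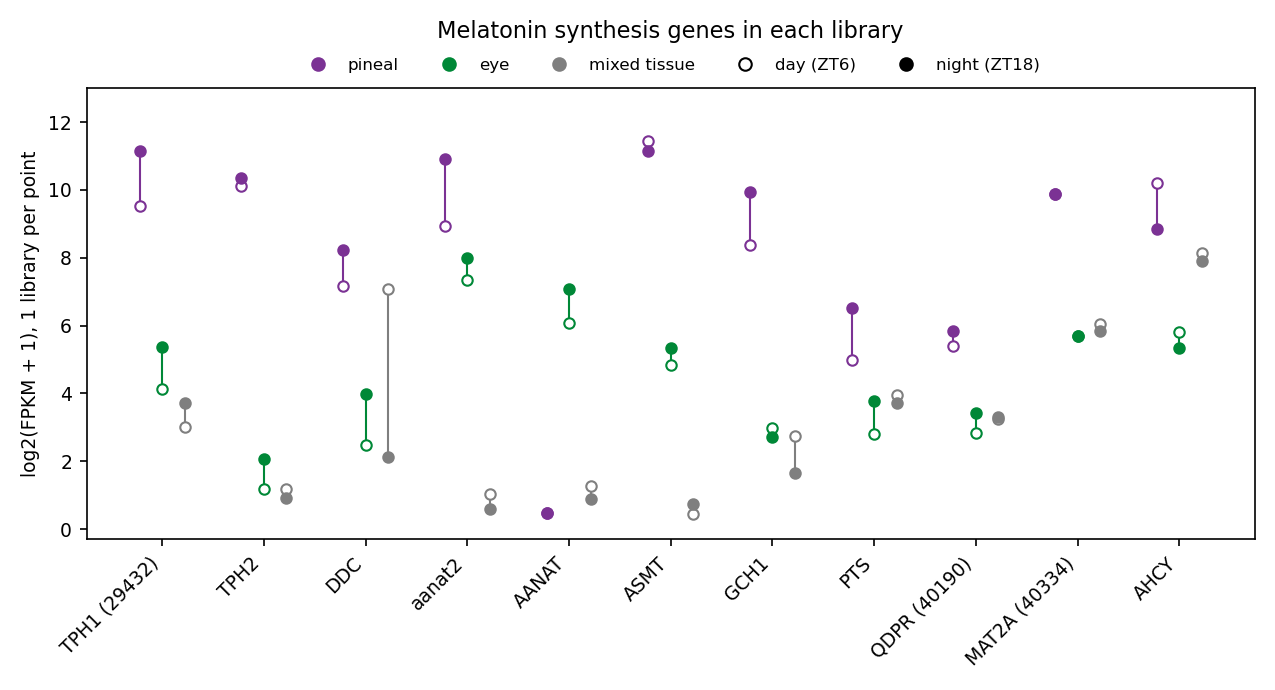
Level of melatonin synthesis genes on the log2(FPKM + 1) axis in each of the 6 libraries, with open circles for day, filled circles for night and a line joining the libraries of a tissue. The pineal libraries (purple) are highest for most genes, AANAT is highest in the eye (green), and aanat2 in the pineal gland goes from 491 FPKM by day to 1922 at night.

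Photoreceptor genes were higher in the pineal gland as a group. Of 31 tested genes of rod phototransduction 27 were higher and 0 lower than in mixed tissue (camera adjusted p 4.95e-15 preset, 0.190 estimated), and of 24 cone genes 20 were higher and 0 lower (4.63e-12 preset, adjusted p 0.154 estimated). Ribbon synapse genes went the same way (13 of 23 higher, camera adjusted p 4.3e-07 preset, 0.154 estimated). So did the list of retinal pigment epithelium and melanocyte genes (17 of 24 higher, adjusted p 6.77e-08 preset, 0.154 estimated), which is not limited to photoreceptor tissue. Non-visual and pineal opsins were higher in 13 of 23 cases and lower in 0 (adjusted p 4.56e-07 preset, 0.154 estimated). RRH (ENSDARG00000039534) was higher by 6.86 (SE 0.28), opn6a (ENSDARG00000102430) by 6.47 (SE 0.29), parapinopsinb (ENSDARG00000044672) by 6.29 (SE 0.23), parietopsin (ENSDARG00000052056) by 6.22 (SE 0.37) and tmtops2a (ENSDARG00000061515) by 5.67 (SE 0.41). Of the visual opsins, 5 of 10 were higher (adjusted p 0.0046 preset, 0.203 estimated), led by the red opsins opn1lw1 (ENSDARG00000044862) at 8.43 (SE 0.24) and opn1lw2 (ENSDARG00000044861) at 7.65 (SE 0.27). Of 30 transcription factors of photoreceptors and the pineal gland, 16 were higher and 1 lower (adjusted p 2.76e-06 preset, 0.154 estimated). bsx (ENSDARG00000068976) was higher by 8.53 (SE 0.25), crx (ENSDARG00000011989) by 8.27 (SE 0.16), LHX4 (ENSDARG00000039458) by 7.99 (SE 0.22) and noto (ENSDARG00000021201) by 5.35 (SE 0.20).

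**Figure D2:**
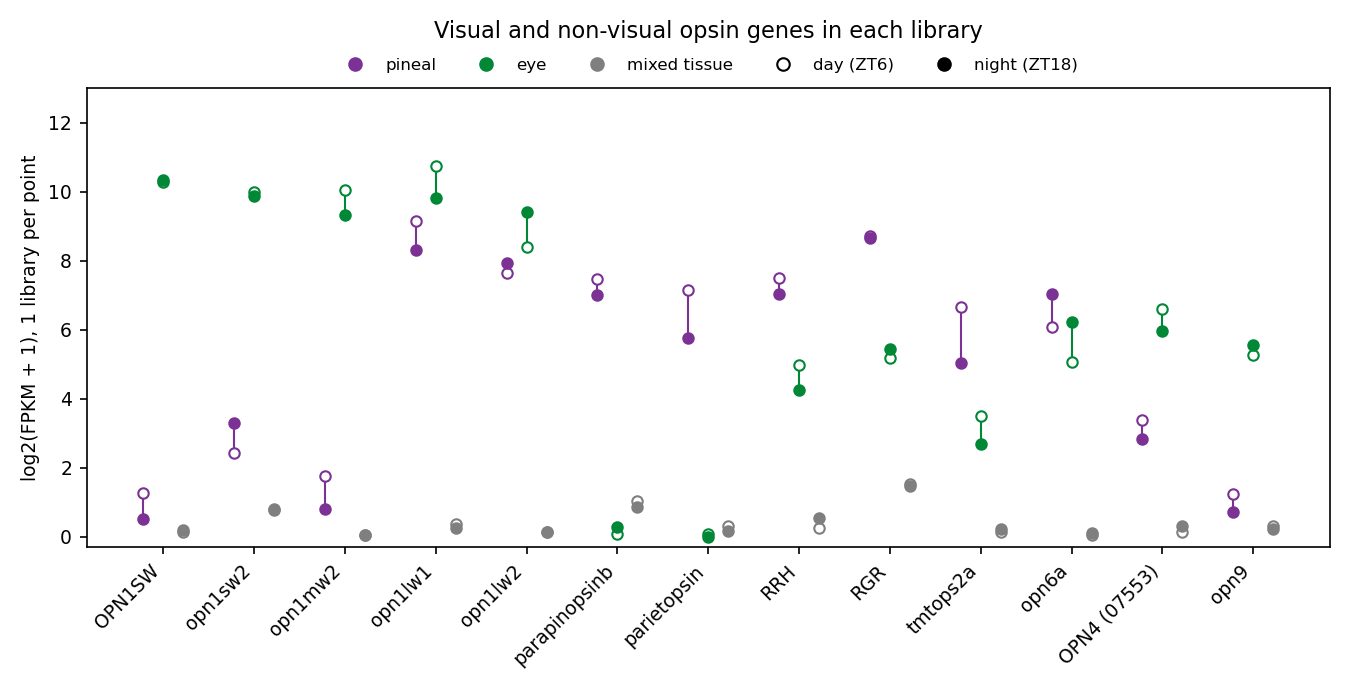
Level of opsin genes on the log2(FPKM + 1) axis in each of the 6 libraries, with open circles for day, filled circles for night and a line joining the libraries of a tissue. OPN1SW, opn1sw2 and opn1mw2 are high in the eye (green) only, opn1lw1 and opn1lw2 are high in eye and pineal gland (purple), and parapinopsinb and parietopsin are high in the pineal gland only.

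In the eye, limma called 10501 genes against mixed tissue, 4424 higher (42.1%) and 6077 lower; quantile normalization gave 5379 higher (50.8%) and 5201 lower. Among the largest rises, CRYGS (ENSDARG00000042992), a lens crystallin, was higher by 10.23 (SE 0.25, limma adjusted p 1.71e-05), OPN1SW (ENSDARG00000045677) by 10.14 (SE 0.26), opn1lw1 by 9.98 (SE 0.24) and GNAT2 (ENSDARG00000042529) by 9.43 (SE 0.18). All 41 tested lens genes were higher than in mixed tissue (camera adjusted p 5.76e-21 preset, 0.345 estimated). So were all 31 rod genes (adjusted p 1.83e-17 preset, 0.169 estimated), 23 of 24 cone genes (6.58e-13 preset, 0.112 estimated) and all 10 visual opsins (5.44e-08 preset, 0.112 estimated). Inner retinal neuron genes were higher in 24 of 27 cases and lower in 1 (adjusted p 1.36e-09 preset, 0.112 estimated). Non-visual and pineal opsins were higher in 19 of 23 cases and lower in 0. Ribbon synapse genes were higher in 21 of 23 and lower in 0. The transcription factors of photoreceptors and the pineal gland were higher in 24 of 30 and lower in 1. The 12 largest falls were again mostly yolk, egg coat and heart muscle genes, from -9.69 for vtg1 (ENSDARG00000092233) to -8.73 for cmlc1 (ENSDARG00000032976). AANAT (ENSDARG00000036567), a second acetyltransferase gene, was higher in the eye by 5.50 (SE 0.36), and aanat2 (ENSDARG00000079802) by 6.84 (SE 0.53).

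Between the pineal gland and the eye, which needs no mixed library as a reference, limma called 4989 genes, 1972 higher in the pineal gland (39.5%) and 3017 lower; quantile normalization gave 2384 higher (48.5%) and 2528 lower. bsx (ENSDARG00000068976) was higher in the pineal gland by 8.61 (SE 0.25) and TPH2 (ENSDARG00000057239) by 8.61 (SE 0.29). The coagulation factor gene F13A1 (ENSDARG00000045453) was higher by 7.30 (SE 0.57), parapinopsinb (ENSDARG00000044672) by 7.06 (SE 0.23), ADM2 (ENSDARG00000078875) by 6.73 (SE 0.43), parietopsin (ENSDARG00000052056) by 6.41 (SE 0.37), the transporter gene SLC6A2 (ENSDARG00000016141) by 6.35 (SE 0.43) and GCH1 (ENSDARG00000070453) by 6.32 (SE 0.60). ASMT (ENSDARG00000098249) was higher by 6.22 (SE 0.23), although the eye libraries held 27.6 and 39.4 FPKM of it. Among the largest falls were the crystallins CRYBB3 (ENSDARG00000041301) at -9.75 (SE 0.31) and CRYGS (ENSDARG00000042992) at -9.75 (SE 0.25), and the opsin OPN1SW (ENSDARG00000045677) at -9.42 (SE 0.26). AANAT (ENSDARG00000036567) was lower in the pineal gland by 6.13 on the log2 scale (value -6.13, SE 0.36). The difference in aanat2 (ENSDARG00000079802) was smaller, 2.26 (SE 0.53, limma adjusted p 0.0270). That call was lost without pineal night (1.34, adjusted p 0.0882), eye day (adjusted p 0.105), eye night (0.126), mixed day (0.0538) or mixed night (0.0542), without a filter (0.0558) and with the libraries of these 2 tissues alone (0.0632). All 41 lens genes (camera adjusted p 1.16e-28 preset, 0.489 estimated), all 10 visual opsins (2.32e-08 preset, 0.381 estimated) and 24 of 27 inner retinal genes (9.21e-14 preset, 0.381 estimated) were lower in the pineal gland. Among the opsins, opn1lw1 and opn1lw2 did not keep that call under every setting. Rod and cone genes went both ways. Of the rod genes 8 were higher and 10 lower, and of the cone genes 6 were higher and 8 lower. So did the 23 non-visual and pineal opsins, with 6 higher and 10 lower in the pineal gland. Of the 30 transcription factors 8 were higher and 15 lower. Ribbon synapse genes were higher in 0 of 23 cases and lower in 11 (camera adjusted p 0.00158 preset, 0.412 estimated). Melatonin genes were higher in 12 of 25 cases and lower in 6 (adjusted p 0.00223 preset, 0.452 estimated).

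The pineal gland and the eye shared 2145 genes that were higher than in mixed tissue. Independent lists of those sizes would share 724.2. Simulated groups with no change that shared the mixed libraries gave 0. With no change hardly any gene can be called in either comparison, so that 0 cannot measure what the shared libraries add to the overlap. Without the mixed night library the count was 1263. Lower in both were 4825 genes (1832.1 for independent lists), while 67 were higher in the pineal gland and lower in the eye (994.8) and 257 the reverse (1333.7). Across genes, which are not independent replicates, the covariance of the log2 values was 2.73, beside 0.0563 in the simulations, a difference of 2.67. The correlation was 0.784 beside 0.498. The mixed libraries were 2 and could not be split with 2 in each part. Part of the excess over independent lists, and over the simulated covariance and correlation, may therefore come from the shared libraries. Single libraries with different mixed controls, counted by size alone, shared 2256 (847.6 for independent lists) and 2048 (731.5) genes at least 2-fold higher.

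Night against day over the 3 tissues gave 0 calls with limma over all 21325 genes, with 1506 genes at an unadjusted p under 0.05. voom on the recovered reads called 11 genes, and limma with a robust prior called 0. The clock list held many of the largest differences. Of its 46 tested genes, 26 passed at 2-fold when adjusted over the list alone, 9 higher and 17 lower at night, and 0 over all genes with limma. voom called 2 of them over all genes, CRY1 (ENSDARG00000045768, adjusted p 0.0148) and nr1d4b (0.0410). The 11 voom calls, 2 higher and 9 lower at night, were thus mostly outside the clock list. They included irg1l (ENSDARG00000062788, voom adjusted p 0.0148), lower at night, and cdkn1a (ENSDARG00000076554, voom adjusted p 0.0258), higher at night. Leaving out either pineal library, day or night, left only eye and mixed tissue to inform the time term. The count over the list alone was then 17. With no tissue term it was 8 (4 higher and 4 lower). nr1d4b (ENSDARG00000059370) was higher at night by 5.89 (SE 0.57, limma adjusted p over the list alone 0.00191, over all genes 0.262), in all 3 tissues. nr1d4a (ENSDARG00000031161) was higher by 5.75 (SE 0.83), NR1D1 (ENSDARG00000033160) by 4.66 (SE 0.51), dbpb (ENSDARG00000057652) by 3.81 (SE 0.54) and PER1 (ENSDARG00000056885) by 2.40 (SE 0.51). On the other side, CRY1 (ENSDARG00000045768) had a value of -3.40 (SE 0.22, limma adjusted p over the list alone 0.000434, over all genes 0.102), below 0 in all 3 tissues. nfil3-5 (ENSDARG00000094965) was at -4.42 (SE 0.86), rorcb (ENSDARG00000017780) at -4.20 (SE 0.78), rorca (ENSDARG00000057231) at -3.24 (SE 0.72), PER2 (ENSDARG00000034503) at -2.69 (SE 0.67) and npas2 (ENSDARG00000016536) at -2.18 (SE 0.58). The 2 genes with the symbol BMAL1 were at -1.83 (ENSDARG00000035732, SE 0.44) and -1.59 (ENSDARG00000006791). By camera, 9 lists were called in this comparison at the preset correlation with 0 of their members called, and none with an estimated correlation (adjusted p 0.781 to 0.824). Over all 4 comparisons 64 of 120 list tests were called at the preset correlation and 0 with an estimated one. That 0 does not show that correlation between genes removes these results, since the setting rests on 2 residual degrees of freedom. For the cone list in pineal against mixed tissue the estimated correlation was 0.0129, near the preset 0.01. Its unadjusted camera p still went from 4.63e-13 to 0.0195.

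**Figure D3:**
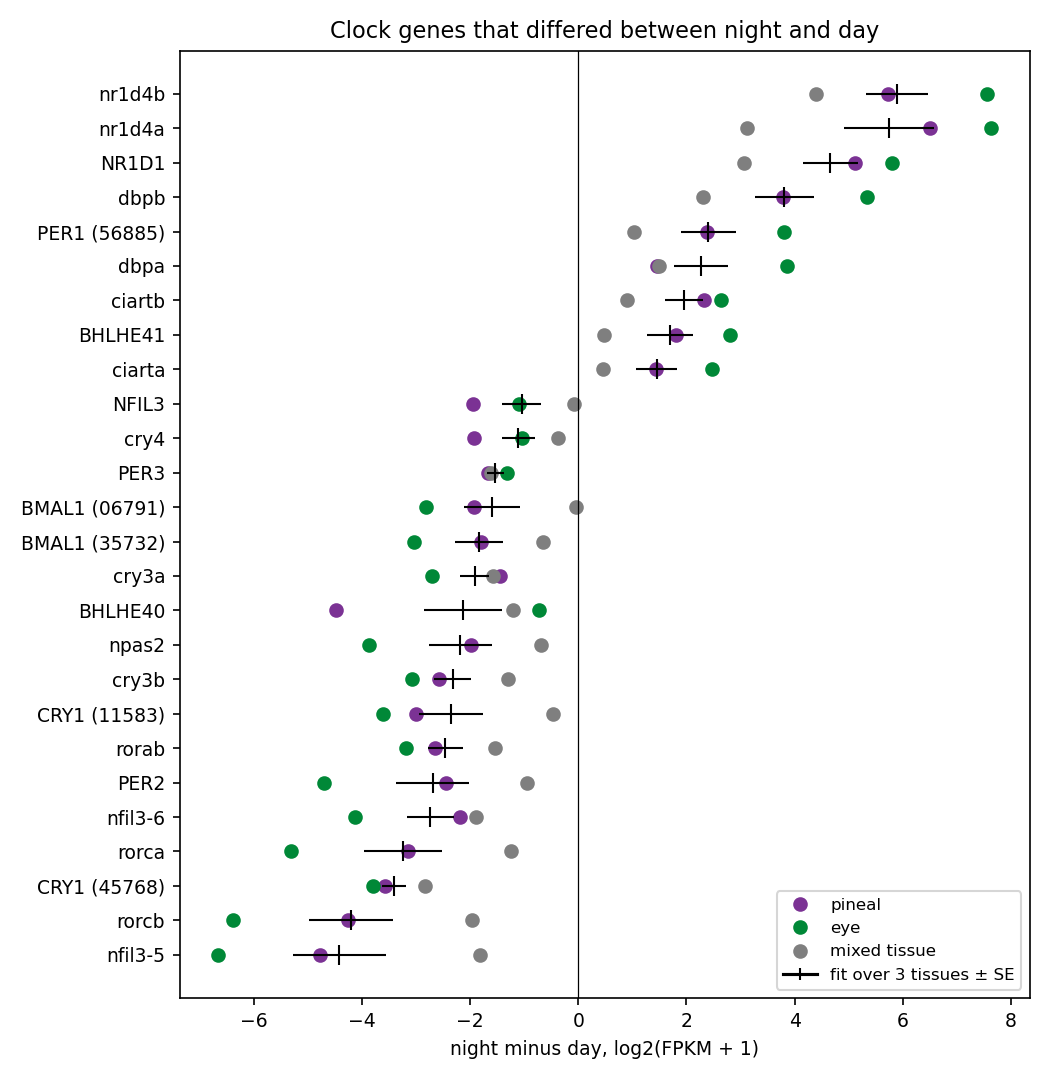
Night minus day on the log2(FPKM + 1) axis for the 26 clock genes that passed when adjusted over the list alone, with 1 point per tissue and the estimate over 3 tissues as a tick with its standard error. Genes with the nr1d4 and dbp names lie to the right in all 3 tissues, CRY1 (ENSDARG00000045768) is at -3.40, and mixed tissue (grey) lies closest to 0 for most genes.

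Within the pineal gland, 628 of 11753 genes differed at least 2-fold between the night and the day library, 280 higher and 348 lower at night. Rescaling by the median ratio turned that split to 340 higher and 290 lower. These and the following within-tissue values compare 2 libraries and have no replicate check. Beside clock genes, the largest rises included cdkn1a (ENSDARG00000076554), from 3.34 to 129 FPKM, SIK1 (ENSDARG00000058606), from 56.2 to 936, NR4A1 (ENSDARG00000000796), from 2.66 to 56.9, and NR4A3 (ENSDARG00000055854), from 1.59 to 42.9. The largest falls included the retinoid-binding gene rbp3 (ENSDARG00000059163), from 1925 FPKM by day to 156 at night, and BHLHE40 (ENSDARG00000004060), from 301 to 12.6. Of 20 immediate early and heat shock genes 10 were at least 2-fold higher at night and 2 lower, with a list median of 0.91 (random lists -0.25 to 0.18). Cholesterol synthesis genes had a median of -0.70 (random lists -0.28 to 0.18), with 17 of 18 below 0. The erythrocyte list had a median of -0.99, with 9 of 9 genes below 0, and the light-induced and DNA repair list of -0.98. These medians kept their sign under both other scalings. Whether the share of blood differed between the 2 pineal pools was not tested. The brain neuron list was also above its range, with a median of 0.33 (random lists -0.28 to 0.20). Of its 14 genes 10 were above 0 and 4 below, and 0 were at least 2-fold higher.

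The eye libraries differed in more genes, 1433 of 12735, with 750 higher and 683 lower at night (648 and 818 after rescaling). The clock genes nr1d4a (ENSDARG00000031161), from 1.71 to 537 FPKM, and nfil3-5 (ENSDARG00000094965), from 337 to 2.36, were among the largest differences. Of the 12 largest rises, 8 were not clock genes. They included epd (ENSDARG00000103498), from 1.57 to 574 FPKM, cbln12 (ENSDARG00000068232), from 0.0602 to 71.0, and ZIC1 (ENSDARG00000015567), from 1.59 to 65.0. A list of brain region genes had a median of 1.02 over 27 members in this comparison (random lists -0.11 to 0.35). Of these, 13 held 5 FPKM or more by day. The others passed the filter only through the night library, so they had to be above 0. Brain RNA in the night eye pool is a candidate source of part of these rises, which this median cannot decide. Without genes at least 4-fold higher in mixed tissue than in the day eye, 1364 genes differed. All 41 lens genes were below 0, 25 of them by at least 2-fold, with a median of -1.05 (random lists -0.26 to 0.14). The lens genes varied nearly as 1 (estimated correlation 0.96), so the range of random lists is too narrow for them. Whether the share of lens differed between the 2 eye pools was not tested. The rod list had a median of -0.64 (random lists -0.32 to 0.15). AANAT (ENSDARG00000036567) was at 67.2 FPKM by day and 135 at night, a ratio of 2.02 (95% exact interval 1.90 to 2.14). GUCA1A (ENSDARG00000101567) was at 168 FPKM by day and 2.56 at night, esrrd (ENSDARG00000015064) at 280 and 9.19, and NDRG1 (ENSDARG00000010420) at 621 and 42.3.

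In mixed tissue 444 of 13055 genes differed at least 2-fold, 102 higher and 342 lower at night. lect2.3 (ENSDARG00000086483) went from 0.269 to 70.4 FPKM and cdkn1a (ENSDARG00000076554) from 1.62 to 41.5. The largest falls were those of NOS2 (ENSDARG00000026925), from 81.3 to 0.484, irg1l (ENSDARG00000062788), from 131 to 1.72, and DDC (ENSDARG00000016494), from 134 to 3.33. The medians of organ lists lay apart, at -0.61 for skeletal muscle, -0.32 for liver and 0.25 for intestine (random lists -0.15 to 0.19 for intestine).

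Day-night differences of the same direction were shared between tissues beyond the number for independent lists. Of 10334 genes with at least 5 FPKM in both, 77 were at least 2-fold higher at night in pineal gland and eye (8.96 for independent lists) and 93 lower in both (11.5). Pineal gland and mixed tissue shared 9 higher (0.365) and 31 lower (2.92), and eye and mixed tissue 12 higher (0.845) and 65 lower (6.06). These comparisons share no library. Genes that went opposite ways exceeded that number too in some cases. Higher at night in the pineal gland and lower in mixed tissue were 10 (1.86), against 9 shared higher, and the reverse was 1 (0.574). Higher in the eye and lower in mixed tissue were 10 (5.11), and the reverse was 1 (1.00). Higher in the pineal gland and lower in the eye were 16 (8.94), and the reverse was 7 (11.5).

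**Figure D4:**
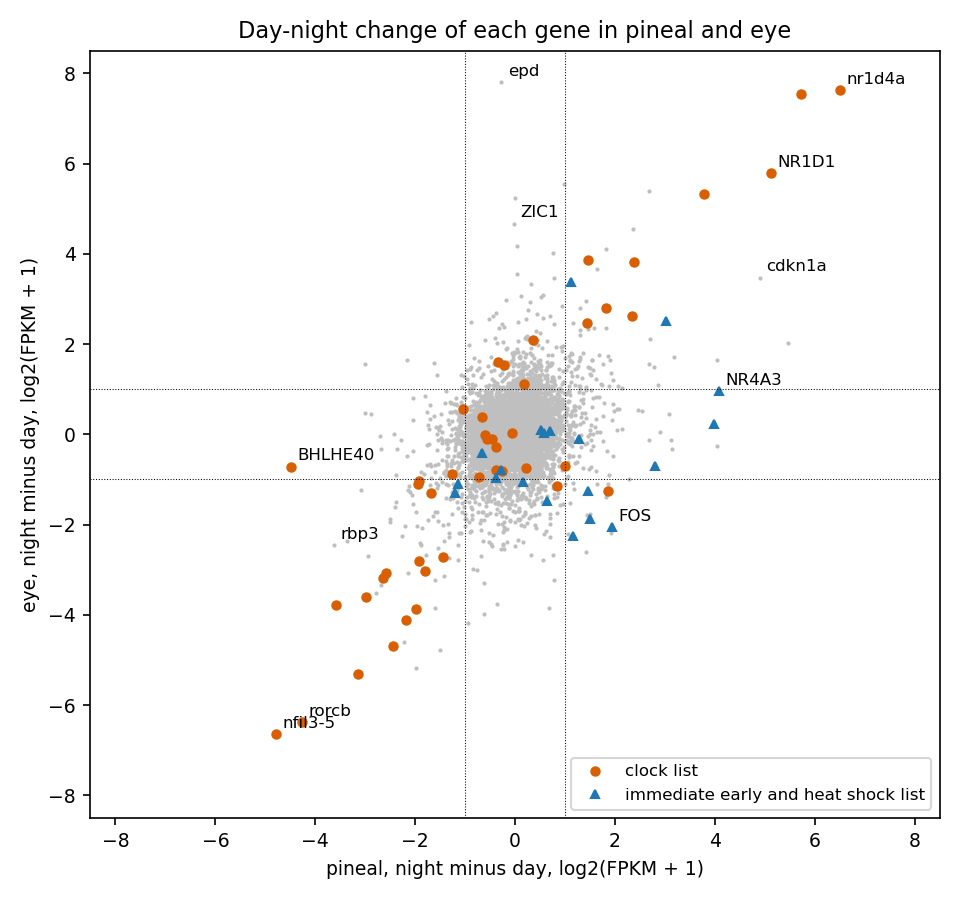
Night minus day on log2(FPKM + 1) axes in the pineal gland (x) and the eye (y) for 10334 genes, with the clock list in orange circles, the immediate early and heat shock list in blue triangles and dotted lines at 2-fold. Clock genes such as nr1d4a and nfil3-5 lie along the diagonal, while NR4A3 and FOS are higher at night in the pineal gland and epd and ZIC1 in the eye alone.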

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

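The tests of the brain region list and of the CREB target list were set down before their results were seen; all other tests in this part were chosen only after the result was seen.

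Of 844 named genes looked at, 12 had at least a 2-fold difference between night and day in 1 tissue and at least a 2-fold difference the other way in another. Each tissue had 1 library by day and 1 at night, and the difference between tissues was not tested. Among all genes there were 40. Values are night minus day on the log2(FPKM + 1) scale. Higher at night in the pineal gland and lower in the eye were BTG2 (1.50 and -1.88), DUSP5 (1.45 and -1.25), FOSB (1.16 and -2.24), fbxl3l (1.86 and -1.26) and plvapb (1.18 and -1.22). FOS had a value of 1.95 in the pineal gland, while its eye libraries held 243 FPKM by day and 57.8 at night. Higher at night in the pineal gland and lower in mixed tissue were GCH1 (1.55 and -1.10) and NR4A3 (4.08 and -1.64), and FOSB too was lower there (-1.98). Higher at night in both the pineal gland and the eye and lower in mixed tissue were rtn4rl2a (3.18, 1.72 and -1.25) and DDC (1.06, 1.51 and -4.96). Higher in the eye at night and lower in mixed tissue was oxt (5.43 and -1.04). ankrd33ab was at 1.55 in the eye and at -3.01 in the pineal gland.

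Several of the largest rises in the night eye library were transcripts of brain genes. Brain RNA in the night eye pool is a candidate source. A list of 51 brain region genes had a median of 1.02 in the eye over 27 members, just past the bound of 1. It was 0.94 after rescaling and 0.95 after quantile normalization, below that bound. The day eye held 13 of these 27 at 5 FPKM or more. The others passed the filter only through the night library and had to be above 0, so the median cannot decide. Of the 27, 23 were above 0 and 4 below, and all 4 were among the 13. The most abundant at night differed little, NRGN (60.2 to 70.5 FPKM) and GABRA6 (ENSDARG00000075058, 55.4 to 69.2), unlike ZIC2 (ENSDARG00000015554, 3.84 to 39.4) and pvalb7 (2.26 to 26.5). A night-time rise in brain itself is argued against only if the brain share of the mixed day and night libraries was equal, which was not tested. The 8 largest rises that are not clock genes had a median of 5.32 in the eye and of -0.15 in mixed tissue, which holds brain RNA. The 14 brain region genes at 5 FPKM or more in mixed tissue had a median of 0.11 (random lists -0.18 to 0.17). A difference within the eye between day and night, which the design names, stays open and untested.

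Among the 12 largest falls in the night mixed library were the transporter genes slc47a2.1 and SLC22A2 and the pancreas gene cela1.3. A smaller kidney share at night may be part of the cause: 31 kidney genes had a median of -0.57 (random lists -0.08 to 0.14). As the whole cause of the low transcripts it is argued against, since it would lower no other organ and the skeletal muscle list had a median of -0.61 (17 of 20 genes below 0, random lists -0.13 to 0.16). Unequal shares of organs between the pools may also contribute, as organ list medians lay 0.87 apart. The pools were described as equal amounts of RNA from each organ. A difference within an organ between day and night stays open and untested, and list medians cannot tell it from unequal shares. The kidney explanation was divided into a part and a whole, and muscle chosen for the latter, only after the results were seen, and NOS2 and irg1l were also lower at night in the pineal gland and the eye.

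Immediate early genes were high in the night pineal library. Handling of the night fish in all tissues is argued against, since this list's medians were -0.56 in the eye, the lower, and -0.34 in mixed tissue. Random lists ranged from -0.18 to 0.28 in the eye and from -0.10 to 0.17 in mixed tissue. A day level raised for another reason could still hide a rise at night in these tissues. Whether cAMP signalling in the pineal gland at night may be the cause cannot be told apart from other causes: 17 other CREB targets had a median of 0.11 (random lists -0.26 to 0.20), with 5 at least 2-fold higher and 0 lower. Handling of the pineal glands alone was not tested.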

How the results depend on the processing

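The voom and robust prior settings, the clock list adjusted on its own and the eye without genes far higher in mixed tissue were chosen only after results were seen.

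No call of a tissue comparison changed direction under any setting run. Leaving out 1 library in turn gave 7061 to 10066 genes for pineal against mixed tissue, 7673 to 11007 for eye against mixed tissue and 3485 to 4975 for pineal against eye; the lone library left in a group was assumed to vary like the others. Genes higher in both ranged from 1263 (without mixed night) to 2227 (without eye day), and numbered 3332 with no fold threshold. Night against day gave 0 calls with limma in all these settings (1506 genes at an unadjusted p under 0.05) and 11 with voom. For night against day, leaving out 1 library leaves its tissue without a pair, so each such run rests on the remaining tissues. Clock genes passing over the list alone then ranged from 17 (without pineal day or pineal night) to 26. They were 8 with no tissue term and 27 with no fold threshold. Of 64 list tests called, 0 were called with an estimated correlation. That setting rests on 2 residual degrees of freedom, so it cannot separate the effect of correlation between genes.

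Within tissues the counts moved with the thresholds. The pineal gland had 947 genes at 1 FPKM or more, 327 at 20 FPKM or more and 191 at 3-fold. Mixed tissue had 696, 172 and 147. The eye had 710 at 20 FPKM or more, 534 at 3-fold and 1364 without genes at least 4-fold higher in mixed tissue.

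Of 2208 values for named genes in tissue comparisons, 26 lost their call, in 8 results, among them aanat2, opn1lw1 and opn1lw2 between pineal and eye, and PTS, AHCY, ASMTL and asmt2 between pineal and mixed tissue. Of 408 values for night against day, 2 gained one, both with voom. Of 513 within-tissue values, 103 moved beyond counting error, 82 of them away from 0.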

Other observations

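The splits of the libraries, and the comparison of eye levels with mixed-tissue levels, were tests chosen only after the result was seen.

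The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. For night against day the real split gave 0 genes with limma (1506 at an unadjusted p under 0.05, 11 with voom) and the highest other gave 11. Counting the real one, 10 splits gave as many, which was fixed since no split can give fewer than 0. For clock genes over the list alone the real split gave 26 and the highest other 2, so 1 split, the real one, gave as many. Only 4 of the 10 splits place 1 library of each tissue on either side, and among these the highest other was 0 genes and 1 clock gene. In the others of these 4, a day-night difference shared by the tissues enters the residual, which lowers their counts. They therefore cannot measure how often 26 clock genes would pass without such a difference. The other 6 place both libraries of a tissue together, so with tissue terms each rests on the day-night difference of 1 tissue; the splits with 11 genes rest on the eye.

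In the brain region list, 18 genes were under 2 FPKM in the day eye and at 1 FPKM or more in mixed tissue. Their gain in the night eye had a median of 1.104 times the mixed-tissue level, with quartiles of 0.382 and 2.29. These genes were picked for a low day level, which favours a gain. Brain was only part of the mixed pool, so the ratio does not give the share of brain RNA in the eye pool. Brain RNA in the night eye pool may account for such a median, while the spread leaves room for other sources. The list median of 1.02 does not decide it, since part of the list passed the filter only through the night library. cyp11c1 went from 0.749 to 72.8 FPKM in the eye and was near 0 in mixed tissue, so brain RNA like that in the mixed pool does not account for it.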
